A study of Mus musculus with 6 samples.

How the data were processed

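RNA from whole mouse testes on day 10 was measured in 6 libraries, 3 from control animals and 3 from a germ cell conditional knockout of Eif5 (cKO) made with a Stra8-Cre driver, per the series description. The genotype of the controls is not stated in the labels, so an effect of the Cre or of the floxed alleles is not separated from that of the loss of Eif5. The groups and replicate numbers were taken from the sample titles. Total RNA was isolated with a column kit and libraries were made with a mRNA library kit, per the labels' protocols. StringTie 1.3.1 and RSEM are named in the submitters' processing notes, with no role given. The aligner, the genome build, the annotation and the strand setting are not given in the sources used here.

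The authors deposited 1 table of 22219 gene symbols with 1 column of values per library, and all 6 columns were used. The table is named for raw counts, but its deposited values form a normalised signal: in each column 100% of the values were whole multiples of 1 step, within a tolerance of 1e-06. The inverse of each step equalled the median-of-ratios size factor recomputed from the recovered whole reads, so each value was a read count divided by 1 size factor per library, between 0.825 and 1.35. These values are called normalised read counts here. The lowest total of recovered reads over the 6 libraries was 10, so genes under that total were not in the table. Among recovered counts of 1 to 20, 78.1% were even (75.1% to 80.9% per library), so the recovered reads were not a sum of independent single events at the low end. Recovered totals ran from 32555443 to 48409550 reads per library.

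The design fixed in advance assumed raw counts and edgeR's quasi-likelihood test. Because the values were already scaled, the test used throughout was limma 3.58.1 with an intensity-dependent prior on log2(value + 2), 2-sided, for cKO against control with no covariate. Fold changes are on this log2(value + pseudocount) scale, which understates the change of genes at low levels. edgeR 4.0.16 (quasi-likelihood, with its default scaling factors) was run on the recovered reads as an added alternative. Genes were filtered with edgeR's filterByExpr on the recovered reads (minimum count 10), which left 17570 genes and took out 4649. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. A fold change of at least 2 was used as a further size limit. R 4.3.3 was used. Nothing in the labels says that the 3 libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

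On simulated counts for the 17570 genes of this comparison, limma recovered 50.7% of 67 genes changed 1.5-fold, 73.1% of 67 changed 2-fold and 89.4% of 66 changed 4-fold, and 2.58% of the calls were false. edgeR recovered 52.2%, 74.6% and 92.4%, with 3.75% false calls. A simulated list of 40 genes raised 1.3-fold had a camera p of 6.25e-26 and an unshifted list of 40 genes had a p of 0.902. Genes were simulated independently of each other, whereas the correlation estimated within the real lists reached 0.897. The simulation therefore does not show how camera behaves where the genes of a list move together. It changed a far smaller share of genes than the 20.04% called in the real data, and its counts had no excess of even values. Its recovery and false call rates may therefore differ from those of the real comparison. No pair of libraries was a duplicate: the chi-square per degree of freedom between libraries was 10.02 or more.

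The comparisons, the gene lists, the rule for named genes and most of the other settings were fixed before the data were examined. The 26 gene lists covered germ cell stages (spermatogonial stem cells, progenitor spermatogonia, differentiating spermatogonia, meiotic prophase, germline piRNA pathway, late spermatocytes and spermatids), other cells of the organ or its surroundings (Sertoli cells, Leydig cells, peritubular myoid cells, stromal fibroblasts, macrophages, endothelial cells, erythroid cells, mesothelium and epididymis) and processes (integrated stress response, ER chaperones and ERAD, p53 targets, apoptosis machinery, homologous recombination and Fanconi repair, excision, mismatch and end-joining repair, translation initiation factors, cytosolic ribosomal proteins, cell cycle and replication, interferon and inflammation, mitochondrially encoded genes, immediate early and heat shock). No gene was in more than 1 list. Of 652 members, 645 were matched by symbol or by a RefSeq GRCm38.p6 synonym, and 634 passed the filter. GENCODE M21 held 94.2% of the symbols. It was used for names, transcript length, GC content and chromosome, and no coordinates are given because the build of the table is not given.

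Each list was tested with limma's camera on the same log2 values with a preset inter-gene correlation of 0.01, adjusted over the 26 lists. camera asks whether a list moved relative to the other genes. With a correlation estimated from the 6 libraries, 0 of the 26 lists were called and 15 were called with the preset one. Calls also ended for the stem cell and apoptosis lists, whose estimated correlations (-0.0287 and 0.000596) lay below the preset 0.01. A higher correlation alone therefore does not account for all of these losses. With an estimated correlation camera also uses the few residual degrees of freedom of the 6 libraries, so the same statistic gives a larger p. A call lost this way therefore does not by itself show that correlation within the list had made the call. limma's fry was also run: its directional p tests whether the genes of a list move, on balance, one way, its mixed p tests whether they change in either direction, and neither compares a list with other genes. fry called 15 lists by the directional p and 22 by the mixed p.

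Genes named are Eif5; the 6 genes with the largest rise and the 6 with the largest fall among called genes whose groups did not overlap and whose higher group averaged at least 2 CPM, leaving out predicted and unnamed genes (symbols beginning with Gm and a digit or ending in Rik), clone names and pseudogenes; and the 2 members of each list with the smallest p, or 1 where no member was called. In the lists the p was limma's. The result of 1 of the 6 largest rises is not reported here. Gfra1, Ret, Lhx1, Ccnd2, Sox3, Gapdhs, Hspa2, Rhox5, Atf4, Trib3, Herpud1, Derl1, Tmbim6, Dnajb11, Tap1, Sesn1, Zmat3, Pidd1, Xpc, Apaf1, H2afx, Jun, Hspa1a, Ier2, Hspa5, Rhox13, Fmr1nb, Tex11 and Taf7l were chosen after their values were seen. The alternatives were other scaling factors (TMM, upper quartile, library totals, the summed reads of the Sertoli cell list), other filters, pseudocounts of 0.5 and 10, DESeq2 1.42.0, limma voom, edgeR, edgeR on halved reads, the replicate number as a block, leaving out each library, an adjusted p of 0.01, and the other list tests.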

Results

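Gene expression was measured in whole testes of day 10 mice, 3 control libraries and 3 libraries from animals in which Eif5 was deleted in germ cells (cKO). Whether the controls carried the floxed alleles or the Cre is not stated in the labels. Recovered reads came to 48409550, 33631996 and 35392214 in control replicates 1 to 3 and to 35344558, 48015318 and 32555443 in cKO replicates 1 to 3. Between 20841 and 21582 genes were detected per library. The first principal component carried 39.96% of the variance and separated the groups. Correlations of log2 values between libraries were 0.986 to 0.988 within groups and 0.978 to 0.982 between them. The share of reads from mitochondrially encoded genes was 6.16%, 4.41% and 9.64% in the controls and 7.95%, 6.39% and 7.93% in cKO. The comparison asked how loss of eIF5 in germ cells changed the testis transcriptome. The processes named in the title of the study are endoplasmic reticulum stress, DNA repair and the death of early spermatogonia.

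Eif5 itself, which encodes the GTPase-activating protein of the translation preinitiation complex, fell from 11234 ± 708 normalised read counts (SD, n = 3) in control testes to 9035 ± 515 in cKO (SD, n = 3). The log2 fold change was -0.31 (SE 0.0947, limma adjusted p = 0.024), and all 3 cKO libraries lay below all 3 controls. Scaled to the Sertoli cell list it was -0.71, the largest size over the settings tried, and -0.27 without control replicate 1, the smallest. The gene is kept in the somatic cells of a whole testis, and reads outside the deleted part of the gene were not separated from those within it. The call ended without cKO replicate 1 (adjusted p = 0.13) and without cKO replicate 2 (adjusted p = 0.0875).

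The largest falls under the naming rule began with Gal3st1. This gene, the sulfotransferase of seminolipid synthesis, fell from 451 ± 69.4 to 36.7 ± 3.48 normalised read counts (log2 fold change -3.54, SE 0.204, limma adjusted p = 6.73e-10; SD, n = 3 per group). The X-linked Magea4 (-3.41), the serine protease gene Prss41 (-2.78), Ly6k, a member of the list of differentiating spermatogonia (-2.59), the X-linked deubiquitinase gene Otud6a (-2.56) and the X-linked homeobox gene Esx1 (-2.47) fell by amounts given as log2 fold changes. Magea4 belongs to a family of similar copies, so its value is uncertain where reads were shared. The largest rises were in Chac1, which encodes a glutathione-degrading enzyme (2.95), Slc7a3, a cationic amino acid transporter gene (2.73), Cox6a2, a cytochrome c oxidase subunit gene of muscle (1.69), Cbln4, a cerebellin gene (1.56), and Helt, a transcription factor gene (1.28).

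**Figure D1:**
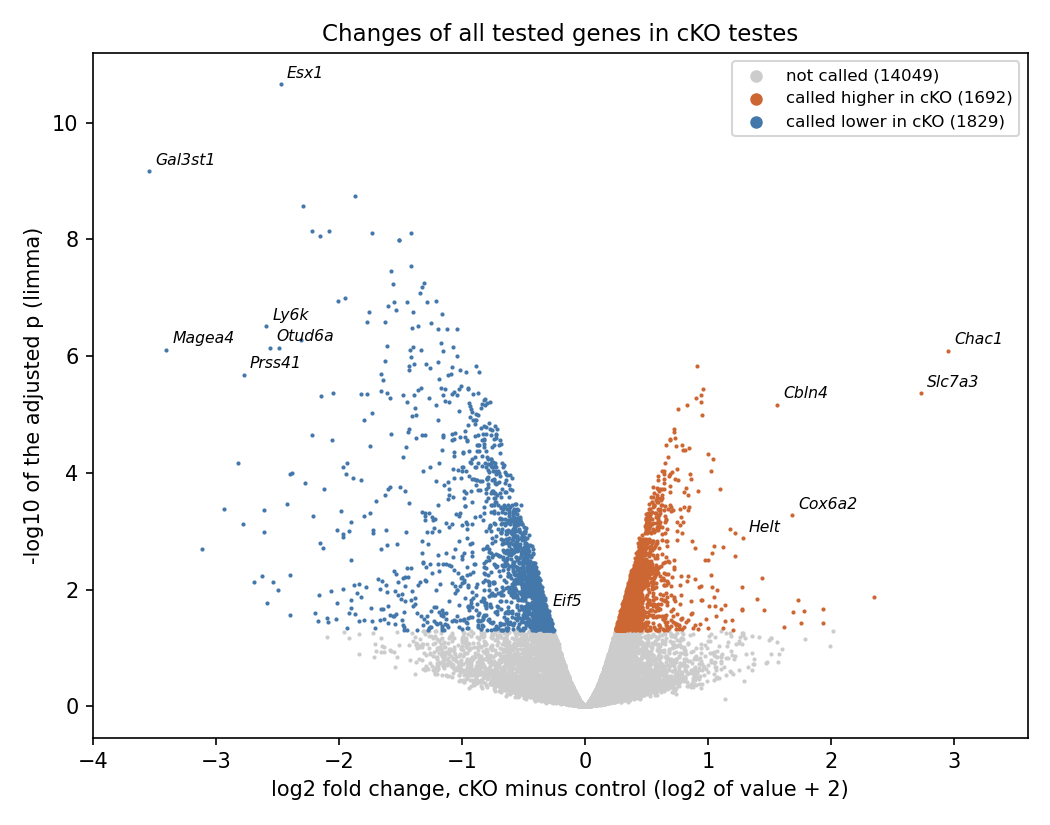
Log2 fold change of each of the 17570 tested genes (x axis) against the -log10 of its limma adjusted p (y axis), with the 1692 genes called higher, the 1829 called lower and the others in separate colours. Eif5 and genes with the largest rises and falls under the naming rule are labelled, from Gal3st1 at -3.54 to Chac1 at 2.95.

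Of 17570 genes tested, 1692 were higher and 1829 lower in cKO by limma, 20.04% in all. edgeR on the recovered reads called 1575 higher and 1857 lower, and 3336 genes were called by both in the same direction. The falls were larger than the rises: 342 genes fell and 43 rose at least 2-fold. The median log2 change was 0.41 among genes called higher and -0.55 among genes called lower. The groups did not overlap for 36.7% of the tested genes, where chance gives 10%. How the calls split depended on the scaling. With the deposited factors 51.9% of the calls were lower, with library totals alone 75.6% (807 higher, 2495 lower), and with scaling to the Sertoli cell list 99.4% (27 higher, 4556 lower). The last of these moved the median log2 fold change of all genes to -0.39, against 0.01 with the deposited factors. Counts of lower genes and list medians under it include that shift. It leans heavily on Clu, the Sertoli member with the most reads, which was itself not called (log2 fold change 0.39, limma adjusted p = 0.217). Of the genes named as higher, Chac1, Slc7a3, Cox6a2, Cbln4, Helt, Gdnf and Trib3 were also called higher under the Sertoli scaling and the others were not. The number called higher dropped to 916, 1005 and 938 without cKO replicate 1, 2 or 3.

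With the deposited factors germ cell stages moved in different directions, while under the Sertoli scaling 0 members of any germ cell list were higher. Genes of meiotic prophase fell nearly throughout: 36 of 38 tested members were lower and 0 higher, with a median log2 fold change of -1.34. Stag3, which encodes a meiotic cohesin subunit, fell from 4370 ± 523 to 1629 ± 59.4 normalised read counts (log2 fold change -1.42, SE 0.0990, limma adjusted p = 7.83e-09; SD, n = 3 per group), and the meiotic regulator Meioc, listed as Gm1564, had a log2 fold change of -2.22. Genes of differentiating spermatogonia fell as well, with 11 of 12 members lower and a median of -1.08. Among them were Stra8, the retinoic acid-induced gene whose promoter drives the Cre (-1.73), and the protease gene Prss50 (-2.29). In the germline piRNA pathway 15 of 22 members were lower (median -0.44), including Tdrkh (-0.94) and Tex14, a gene of germ cell bridges (-0.84). The list of late spermatocytes and spermatids, stages rare at this age, had 4 of 13 members lower: Clgn (-1.14), Ybx2 (-1.07), Gapdhs (-1.15) and Hspa2 (-0.41). Lower genes numbered 37 meiotic, 12 differentiating, 18 piRNA and 4 late ones when adjusted over the list alone. The camera adjusted p was 1.92e-43 for meiotic prophase, 1.34e-15 for differentiating spermatogonia, 5.14e-11 for the piRNA pathway and 0.0096 for the late list. With an estimated correlation the camera adjusted p was 0.0986, 0.0876, 0.185 and 0.178, in the same order, and these calls were lost. The late list was not called under the Sertoli scaling (adjusted p = 0.064). Among the 10 ways to divide the 6 libraries into 3 and 3, the preset test called 15 lists for the genotypes and up to 17 for another division. Of the 15 lists, 9 had their smallest camera p in the division by genotype, among them meiotic prophase (7.37e-45 against 2.08e-14 at the lowest elsewhere). The margin was small for the integrated stress response (4.19e-10 against 3.38e-09), stem cells (0.00406 against 0.00825) and apoptosis machinery (0.0173 against 0.0336). The lists of late spermatocytes and spermatids, Leydig cells, macrophages, excision repair, inflammation and early response had a smaller camera p in another division. All divisions other than that by genotype had both genotypes on each side. Each kept part of the genotype difference, so its p is not that of libraries without a genotype effect. Without control replicate 1 the late list had 2 members lower. The call of Gapdhs ended without control replicate 1 or 2 or cKO replicate 2 (adjusted p = 0.077, 0.0895 and 0.136) and that of Hspa2 without control replicate 1 or cKO replicate 1 or 3 (adjusted p = 0.154, 0.0551 and 0.174).

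Spermatogonial stem cell genes stood apart from these. Their list rose (camera adjusted p = 0.0096, or 0.178 with an estimated correlation), with 5 of 16 members higher, 0 lower and a median of 0.38. Scaled to the Sertoli cell list the median was -0.02, against -0.39 for all genes, and camera still called the list higher. Unadjusted, its camera p was 0.00406 by genotype and 0.00825 at the lowest in other divisions of the libraries. Etv5, a transcription factor gene of stem cell self-renewal, rose from 965 ± 68.9 to 1485 ± 92.6 normalised read counts (log2 fold change 0.62, SE 0.104, limma adjusted p = 0.000294; SD, n = 3 per group). Bcl6b (0.82), the GDNF receptor genes Gfra1 (0.59) and Ret (0.38; -0.02 under the Sertoli scaling) and the transcription factor gene Lhx1 (0.74) were the other members called. Lhx1 was not called by edgeR or DESeq2 (adjusted p = 0.0735 and 0.0706). Each of these methods called 4 members of the list higher and 1 lower. Under the Sertoli scaling 0 members of the list were higher and 2 lower, and with library totals 3 were higher and 1 lower. With the deposited factors progenitor spermatogonia genes were split: Tcl1 (0.75) and Ccnd2 (0.46) rose, Rarg, a retinoic acid receptor gene (-0.55), and Sox3 (-0.52) fell, and 8 of 12 were not called (median -0.28, camera adjusted p = 0.172). With library totals 2 progenitor genes were higher and 6 lower, and under the Sertoli scaling 0 were higher and 7 lower (median -0.68), with Tcl1 (0.35) and Ccnd2 (0.06) not called. Adjusted over the list alone, 5 stem cell genes were higher and 1 lower, and 2 progenitor genes were higher and 6 lower. The progenitor list was called lower without cKO replicate 2 (adjusted p = 0.0497). It had 5 members lower without control replicate 3 or cKO replicate 2 and 1 without cKO replicate 3 (median -0.16), and the stem cell list had 3 higher without control replicate 3, cKO replicate 1 or cKO replicate 3. The call of Ret ended without control replicate 1 or 3 or cKO replicate 1 or 3 (adjusted p = 0.173, 0.0658, 0.19 and 0.095). That of Lhx1 ended without control replicate 2 or 3 or cKO replicate 1, 2 or 3 (adjusted p = 0.0784, 0.174, 0.119, 0.109 and 0.0844), and that of Sox3 without cKO replicate 3 (adjusted p = 0.0543).

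**Figure D2:**
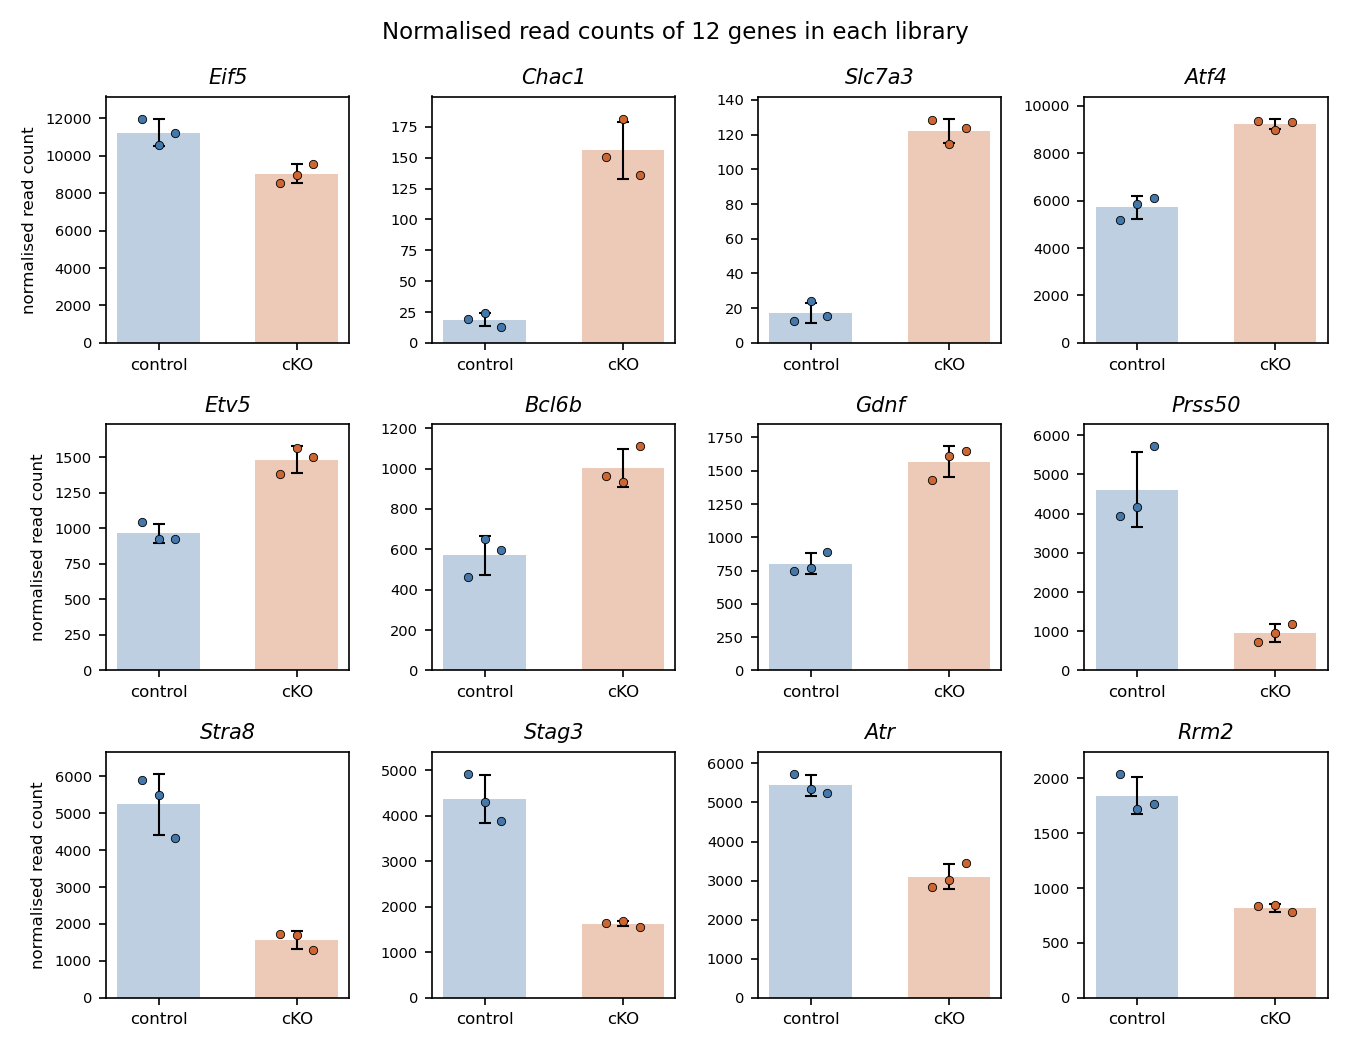
Normalised read counts (y axis, linear from 0) of 12 genes in control and cKO testes, with 1 panel per gene, points for the 3 libraries of each group, bars for their mean and error bars for 1 SD. Eif5 lies at 11234 in control and 9035 in cKO, Chac1 at 18.8 and 156, Gdnf at 803 and 1566, and Stra8 at 5237 and 1574.

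Genes of Sertoli and Leydig cells rose. In the Sertoli list 9 of 18 members were higher, 1 lower, and the median was 0.41 (camera adjusted p = 1.37e-06; adjusted p = 0.188 with an estimated correlation). Gdnf, the growth factor that maintains spermatogonial stem cells, rose from 803 ± 78.2 to 1566 ± 117 normalised read counts (log2 fold change 0.96, SE 0.109, limma adjusted p = 3.67e-06; SD, n = 3 per group), and Fshr, the receptor for follicle-stimulating hormone, had a log2 fold change of 0.64. The homeobox gene Rhox5 fell (-0.51). In the Leydig list 9 of 12 members were higher and 0 lower (median 0.46; camera adjusted p = 5.65e-07; adjusted p = 0.16 with an estimated correlation), among them the steroidogenic gene Hsd17b3 (0.63) and Lhcgr, the receptor for luteinizing hormone (0.70). Scaled to the summed reads of the Sertoli cell list, the medians of the Sertoli and Leydig lists were 0.01 and 0.06, and 2 Sertoli members were still called higher, among them Gdnf (0.57), and 1 lower. Of the Leydig genes 0 were called under that scaling, with Hsd17b3 at 0.23 and Lhcgr at 0.30. The macrophage list was called higher, with 7 of 16 members higher, among them C1qc (0.45) and Ptprc (0.64), and a median of 0.30 that became -0.10 under the Sertoli scaling (camera adjusted p = 0.000539; adjusted p = 0.311 with an estimated correlation). In the Sertoli list 12 genes were higher and 1 lower when adjusted over the list alone, and 9 Leydig and 10 macrophage genes were higher. The number of macrophage genes called higher was 1 without control replicate 1 or 2, 0 without cKO replicate 1 or 2, 4 without cKO replicate 3 and 0 with library totals, and the camera p of the list was 7.94e-10 in another division of the libraries against 0.000186 by genotype. The call of Rhox5 ended without control replicate 2 or cKO replicate 1 (adjusted p = 0.0642 and 0.051). That of C1qc ended without control replicate 1 or 2 or cKO replicate 1 or 2 (adjusted p = 0.115, 0.0853, 0.0965 and 0.0701), and that of Ptprc without control replicate 2 or 3 or cKO replicate 1, 2 or 3 (adjusted p = 0.0559, 0.0712, 0.0841, 0.104 and 0.066).

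Other cell types of the organ did not pass as lists. Of peritubular myoid genes 2 of 10 were lower, the contractile genes Actg2 (-0.43) and Cnn1 (-0.35), with a median of -0.15 (camera adjusted p = 0.164). Under the Sertoli scaling 6 myoid genes were lower, with a median of -0.55. Of fibroblast genes Pdgfra (0.42) and Dcn (0.42) were higher, 2 of 10, with a median of 0.19 that became -0.21 under the Sertoli scaling, where 0 were higher and 3 lower and both genes read 0.02 (camera adjusted p = 0.147). Of 12 endothelial genes Cdh5 was higher (0.36; -0.04 under the Sertoli scaling) and Egfl7 lower (-0.48), with a median of -0.05 (camera adjusted p = 0.589), and under that scaling 0 were higher and 2 lower, with a median of -0.45. The list's direction turned without control replicate 3 (median 0.03, adjusted p = 0.896), and its median was -0.16, -0.09 and -0.10 without control replicate 1, cKO replicate 1 or cKO replicate 3. The erythroid list had 2 of 9 members higher, the globin genes Hba-a1 (0.78) and Hbb-bs (0.65), which have near-identical copies and so uncertain values, and which DESeq2 did not call (adjusted p = 0.144 and 0.24), and a median of 0.49 (camera adjusted p = 0.12). Under the Sertoli scaling the erythroid median was 0.15, with 0 members higher and 1 lower. Hba-a1 read 1070 ± 124 in control and 2010 ± 1103 in cKO (SD, n = 3 per group). In the list of mesothelium and epididymis, tissues next to the testis, the transcription factor gene Pax2 was higher (0.47), 1 of 9, with the median at 0.39, or -0.01 under the Sertoli scaling (camera adjusted p = 0.0764), and Upk3b did not pass (0.42, limma adjusted p = 0.0998). Adjusted over the list alone, 2 myoid genes were lower, 2 fibroblast, 3 erythroid and 1 mesothelial genes were higher, and 1 endothelial gene went each way. The erythroid list was called higher without cKO replicate 2 or 3 (adjusted p = 0.0131 and 0.00494), with 4 members higher in each. It had 0 called and a median of 0.04 without cKO replicate 1 and 0 called without control replicate 3, and 1 higher without control replicate 1 or 2. The mesothelial list was called higher without control replicate 2 or 3 (adjusted p = 0.0445 and 0.04). Without control replicate 3 the fibroblast list had 4 members higher, and without control replicate 1 it had 1 higher and 1 lower, while the endothelial list had 2 lower. The fibroblast median was 0.00 without control replicate 1 and 0.10 without cKO replicate 3, the mesothelial median 0.16 without control replicate 1, and the erythroid median 0.74 without cKO replicate 3. The calls ended for Actg2 without control replicate 3 or cKO replicate 1 or 2 (adjusted p = 0.107, 0.102 and 0.0821) and for Cnn1 without control replicate 2 or 3 or cKO replicate 1, 2 or 3 (adjusted p = 0.0677, 0.14, 0.137, 0.075 and 0.129). The call of Dcn ended without control replicate 1 or cKO replicate 3 (adjusted p = 0.0576 and 0.0885). Those of the endothelial genes ended for Egfl7 without control replicate 2 or cKO replicate 2 (adjusted p = 0.0563 and 0.053) and for Cdh5 without cKO replicate 1 (adjusted p = 0.0544). Those of the globin genes ended for Hba-a1 without control replicate 3 or cKO replicate 1 (adjusted p = 0.0655 and 0.111), and for Hbb-bs without control replicate 1, 2 or 3 or cKO replicate 1 (adjusted p = 0.0524, 0.0551, 0.13 and 0.24). Without cKO replicate 1 their log2 fold changes dropped to 0.36 for Hba-a1 and 0.22 for Hbb-bs.

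**Figure D3:**
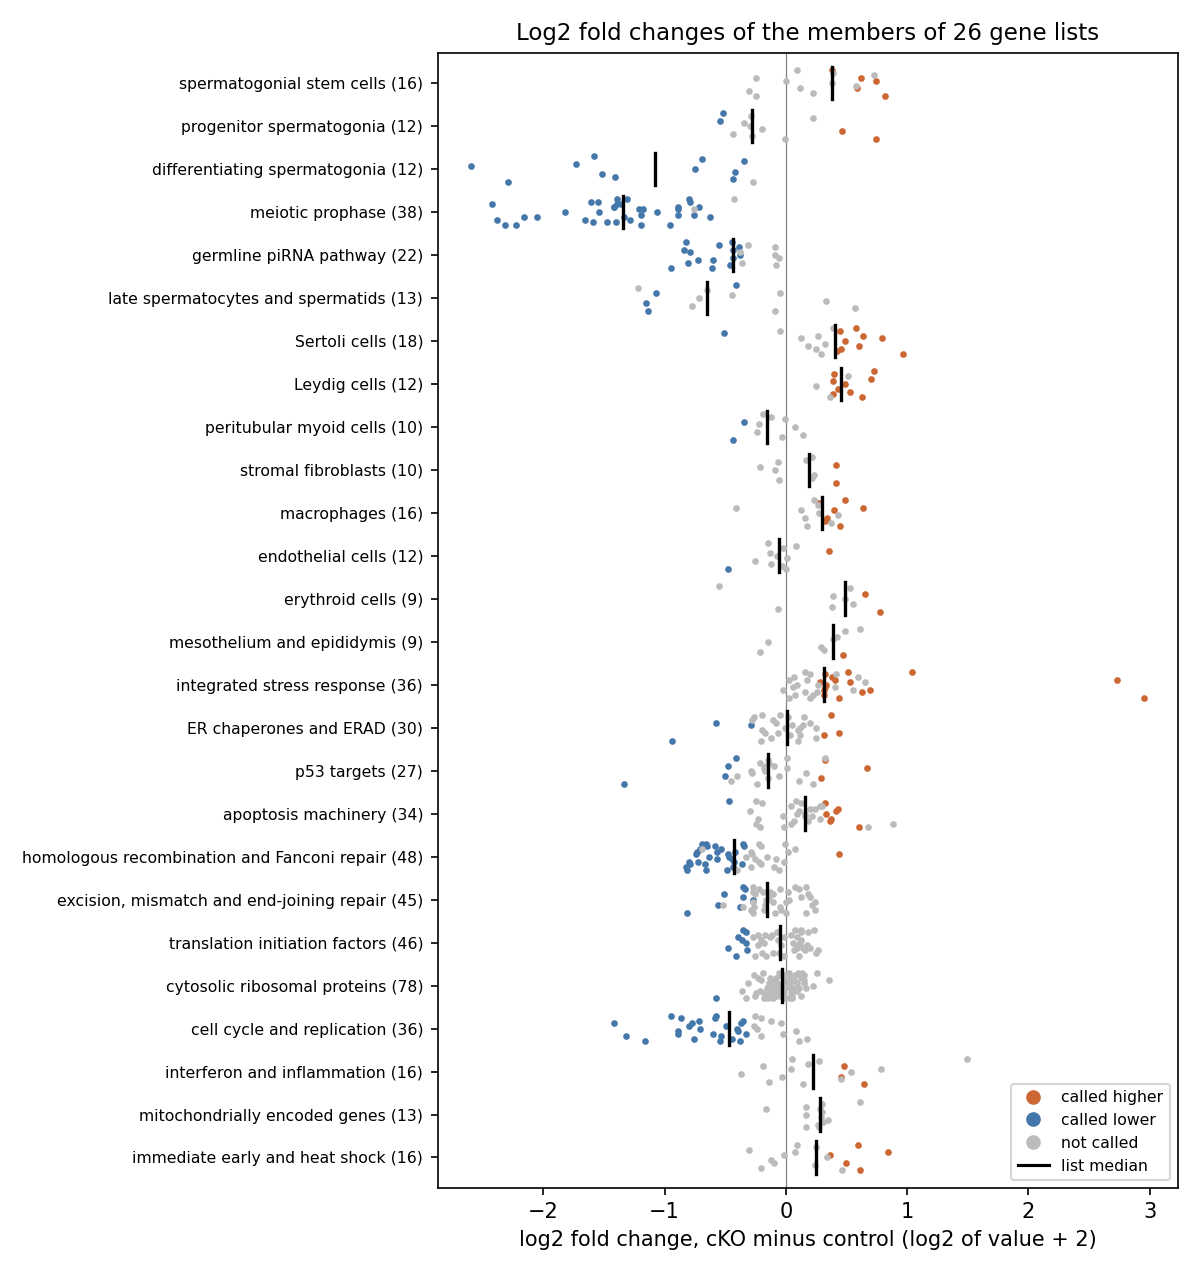
Log2 fold changes (x axis) of the tested members of each of the 26 gene lists (y axis, with the number tested), 1 point per gene, coloured by call, with a vertical bar at the list median. The meiotic prophase list has its median at -1.34 and the stem cell list at 0.38. Scaled to the Sertoli cell list, the stem cell median is -0.02, against -0.39 for all genes. Of the integrated stress response list 3 members lie above 1.

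The integrated stress response, the program driven by the transcription factor ATF4 when translation initiation is held back, rose as a list. Of 36 members 16 were higher and 0 lower, with a median log2 fold change of 0.32. Scaled to the Sertoli cell list the median was -0.08, against -0.39 for all genes, and camera still called the list higher. Chac1 rose from 18.8 ± 5.45 to 156 ± 23.3 normalised read counts (log2 fold change 2.95, SE 0.296, limma adjusted p = 8.06e-07; SD, n = 3 per group) and Slc7a3 from 17.3 ± 5.95 to 122 ± 6.82 (log2 fold change 2.73, SE 0.312, limma adjusted p = 4.35e-06). Atf4 itself (0.69) and Trib3, a pseudokinase gene induced by it (1.04), were also higher. The camera adjusted p was 1.81e-09, and adjusted p = 0.178 with an estimated correlation. Unadjusted, the camera p was 4.19e-10 by genotype and 3.38e-09 at the lowest in other divisions of the libraries. Higher members numbered 20 when adjusted over the list alone. Under that scaling 3 members were called higher, Chac1 (2.57), Slc7a3 (2.36) and Trib3 (0.64). The number called higher was 7 with library totals, 9 without control replicate 1, 6 without cKO replicate 1 and 8 without cKO replicate 2.

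Genes of endoplasmic reticulum chaperones and ERAD did not move as a list. Of 30 members 3 were higher and 3 lower, and the median was 0.01 (-0.08 with library totals, -0.39 under the Sertoli scaling) while the mean was -0.03 and camera's direction was lower (adjusted p = 0.766). The folding genes Sdf2l1 (-0.93), Creld2 (-0.58) and Dnajb11 (-0.29) fell, and Herpud1 (0.44) and Derl1 (0.37; -0.03 under the Sertoli scaling), which act in ERAD, and Tmbim6 (0.31; -0.09 under that scaling) rose. Hspa5, which encodes the main chaperone BiP, read 27333 ± 3451 in control and 23835 ± 2066 in cKO (log2 fold change -0.19, SE 0.117, limma adjusted p = 0.264; SD, n = 3 per group). With p-values adjusted over the list alone, 4 were higher and 4 lower. The list's direction turned without control replicate 3 or cKO replicate 2 (adjusted p = 0.618 and 0.666), and its median was negative without control replicate 1 or 2 or cKO replicate 1 or 3 (-0.02, -0.03, -0.03 and -0.02). The count was 2 higher and 5 lower with library totals, 0 higher and 11 lower under the Sertoli scaling (Herpud1 at 0.04), 2 higher and 6 lower without control replicate 1 and 1 higher and 2 lower without cKO replicate 1. The call of Derl1 ended without cKO replicate 1 (adjusted p = 0.0556). That of Tmbim6 ended without control replicate 1 or cKO replicate 1, 2 or 3 (adjusted p = 0.108, 0.179, 0.132 and 0.106), and that of Dnajb11 without control replicate 2 or 3 or cKO replicate 1, 2 or 3 (adjusted p = 0.0746, 0.0825, 0.101, 0.135 and 0.0743).

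Among genes of cell death, the apoptosis machinery list rose and p53 targets did not pass. In the apoptosis list 7 of 34 members were higher, among them Bok (0.61) and Hrk (0.43), which encode members of the BCL2 family, and Apaf1, the apoptosome gene, fell (-0.47). Its median was 0.16, or -0.24 under the Sertoli scaling (camera adjusted p = 0.0321; adjusted p = 0.178 with an estimated correlation; not called under the Sertoli scaling, adjusted p = 0.126). Of 27 p53 targets 4 were lower, Ddb2 (-1.33), Trp53inp1 (-0.47), Pidd1 (-0.50) and Xpc (-0.41), and 3 were higher, Tap1 (0.67), Sesn1 (0.29; -0.11 under the Sertoli scaling) and Zmat3 (0.32; -0.08 under it), with a median of -0.15 (camera adjusted p = 0.0756). Ddb2 and Xpc act in nucleotide excision repair. Adjusted over the list alone, 7 apoptosis genes were higher and 1 lower, and 3 p53 targets were higher and 5 lower. Apoptosis genes were 3 higher and 2 lower without control replicate 2, 4 higher and 1 lower without cKO replicate 2 or 3, 3 higher and 3 lower with library totals, and 0 higher and 7 lower under the Sertoli scaling. P53 targets were 1 higher and 7 lower with library totals and 0 higher and 14 lower under the Sertoli scaling. Higher p53 targets numbered 1 without control replicate 2 or 3 or cKO replicate 1, 2 or 3. The apoptosis list was not called without control replicate 2 (adjusted p = 0.0569), nor was Apaf1 without control replicate 1 (adjusted p = 0.0614). The calls ended for Xpc without cKO replicate 3 (adjusted p = 0.0543) and for Tap1 without control replicate 1 or cKO replicate 1 (adjusted p = 0.0554 and 0.115). Calls of the others ended for Sesn1 without control replicate 2 or 3 or cKO replicate 2 or 3 (adjusted p = 0.0918, 0.0606, 0.191 and 0.0925), and for Zmat3 without control replicate 2 or 3 or cKO replicate 1, 2 or 3 (adjusted p = 0.164, 0.0804, 0.0593, 0.127 and 0.181).

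Genes of homologous recombination and Fanconi repair fell, as did a part of the genes of other repair pathways. In the list of homologous recombination and Fanconi repair 28 of 48 members were lower and 1 higher, with a median of -0.43, or 40 lower and 0 higher with a median of -0.83 under the Sertoli scaling (camera adjusted p = 3.32e-14; adjusted p = 0.16 with an estimated correlation). Atr, the kinase gene of the replication stress response, fell from 5436 ± 261 to 3097 ± 318 normalised read counts (log2 fold change -0.82, SE 0.0954, limma adjusted p = 5.5e-06; SD, n = 3 per group), and the double-strand break kinase gene Atm had a log2 fold change of -0.73. The member that rose was H2afx, which encodes histone H2AX (0.44; 0.04 and not called under the Sertoli scaling). In excision, mismatch and end-joining repair 8 of 45 members were lower and 0 higher, among them Lig1 (-0.81) and Prkdc (-0.51), with a median of -0.15 (camera adjusted p = 0.0176; adjusted p = 0.418 with an estimated correlation). This second list was not called without control replicate 1 (adjusted p = 0.0554) or cKO replicate 3 (adjusted p = 0.0546). Its lower members numbered 19 under the Sertoli scaling (median -0.55) and 4, 5, 4 and 3 without control replicate 1 or cKO replicate 1, 2 or 3, the last with a median of -0.10. Cell cycle and replication genes fell, with 25 of 36 lower and 0 higher and a median of -0.47, or 30 lower and a median of -0.87 under the Sertoli scaling (camera adjusted p = 1.34e-15; adjusted p = 0.188 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit gene, and Ccne2, the cyclin E2 gene, had log2 fold changes of -1.16 and -1.42. Adjusted over the list alone, 32 recombination genes were lower and 1 higher, and 7 of the other repair genes and 28 cell cycle genes were lower.

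The lists of the translation machinery were not called with the deposited factors. Of 46 translation initiation factor genes 8 were lower and 0 higher, among them Eif5b (-0.41) and Eif1b (-0.39), with a median of -0.05 (camera adjusted p = 0.193). Under the Sertoli scaling 23 were lower and the median was -0.45, against -0.39 for all genes (adjusted p = 0.00701). The number lower was 5 without control replicate 1 or cKO replicate 2 or 3 and 4 without cKO replicate 1, and the median was -0.03 and -0.02 without cKO replicate 2 or 3. Of 78 cytosolic ribosomal protein genes 1 was lower, Rps28 (-0.57; not called by DESeq2, adjusted p = 0.0672), with a list median of -0.03 (camera adjusted p = 0.54). Rps4x had the next smallest p (0.35, limma adjusted p = 0.0507). DESeq2 and edgeR called it higher (adjusted p = 0.00791 and 0.0379), and it was -0.05 under the Sertoli scaling. Under that scaling 57 ribosomal protein genes were lower and the median was -0.43, again against -0.39 for all genes (adjusted p = 5.23e-10). Ribosomal protein genes have processed copies, so single values are uncertain. Of the initiation factor genes 8 and of the ribosomal protein genes 0 were lower when adjusted over the list alone. The ribosomal list was called lower without control replicate 1 (11 members lower, median -0.12, adjusted p = 0.000103), had 0 lower without control replicate 2 or cKO replicate 2, 2 higher without control replicate 3 and 2 lower without cKO replicate 3, and its direction turned without control replicate 2 or 3 or cKO replicate 2 (median 0.02 in each, adjusted p = 0.513, 0.68 and 0.589). The call of Rps28 ended without control replicate 2 or cKO replicate 2 (adjusted p = 0.0526 and 0.06).

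Genes of inflammation and of early responses were higher in part. In the interferon and inflammation list the adhesion gene Vcam1 (0.64) and the NF-kB inhibitor gene Nfkbia (0.48) were among the members that rose, 3 of 16, with a median of 0.23 that became -0.17 under the Sertoli scaling (camera adjusted p = 0.0336; adjusted p = 0.188 with an estimated correlation). In the immediate early and heat shock list, which also moves with tissue handling, Egr2 (0.84), Hspb1 (0.61), Hspa1a (0.60), Jun (0.49) and Ier2 (0.37; -0.03 under the Sertoli scaling) rose, 5 of 16, with a median of 0.25, or -0.15 under that scaling, where 0 were higher and 3 lower and Egr2 (0.45), Hspb1 (0.21), Hspa1a (0.20) and Jun (0.09) were not called (camera adjusted p = 0.0219; adjusted p = 0.188 with an estimated correlation). Of 13 mitochondrially encoded genes 0 were called by limma, and mt-Atp6 had a log2 fold change of 0.27 (adjusted p = 0.357; -0.13 under the Sertoli scaling) with a list median of 0.29, or -0.12 under that scaling (camera adjusted p = 0.14). Adjusted over the list alone, 3 inflammation and 5 early response genes were higher and 0 mitochondrial genes changed. The calls ended for the inflammation list without control replicate 3 or cKO replicate 1 (adjusted p = 0.0721 and 0.0978) and for the early response list without control replicate 3 (adjusted p = 0.0832), where 3 members were higher, as without cKO replicate 1 or 2. The mitochondrial list was called higher without control replicate 3 (7 members higher, median 0.61, adjusted p = 0.000261) or cKO replicate 2 (adjusted p = 0.016) and turned lower without control replicate 2 (median -0.03, adjusted p = 0.807). The inflammation list's median was 0.39 without cKO replicate 3. The call of Hspa1a ended without control replicate 3 or cKO replicate 1 or 2 (adjusted p = 0.0772, 0.0658 and 0.146), and that of Ier2 without any 1 library other than control replicate 2 (adjusted p = 0.105, 0.0953, 0.0841, 0.102 and 0.0558).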

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

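Chosen after results were seen were edgeR on recovered and on halved reads, TMM, and pseudocounts of 0.5 and 10. The cause of a change was not tested except where its construction shows it. With library totals 807 genes were higher and 28 of them at least 2-fold. Erythroid cells (camera adjusted p = 0.0442), mesothelium and epididymis (0.0411) and mitochondrially encoded genes (0.0411) were called higher, and p53 targets (0.0442) lower.

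Scaling to the Sertoli cell list holds the summed reads of that list level by construction, and the median of all genes was -0.39. It left 27 genes higher (10 at least 2-fold) and 4556 lower (1133 at least 2-fold). Values turned negative for Cdh5 (-0.0435), Rps4x (-0.0455), mt-Atp6 (-0.1261), Ret (-0.021), Derl1 (-0.025), Tmbim6 (-0.0855), Sesn1 (-0.1063), Zmat3 (-0.0761) and Ier2 (-0.0316), and the fibroblast list turned (0.958). List calls ended for late spermatocytes and spermatids (adjusted p = 0.064) and apoptosis machinery (0.126). Calls were gained in both directions, each relative to the other genes. Erythroid cells (0.00384), mesothelium and epididymis (0.0137) and mitochondrially encoded genes (0.025) were called higher. Peritubular myoid cells (0.0468), ER chaperones and ERAD (0.0312), p53 targets (0.0335), initiation factors (0.00701) and ribosomal proteins (5.23e-10) were called lower.

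The filter at 1 CPM ended the calls of the apoptosis and inflammation lists (both 0.0739), and voom called mesothelium and epididymis (0.0468). An adjusted p of 0.01 left 706 higher and 1012 lower genes, 19 of the former at least 2-fold. It ended by construction the calls of Eif5 (log2 fold change -0.3139, adjusted p = 0.024), apoptosis (0.0321), excision repair (0.0176), inflammation (0.0336) and early response (0.0219). A pseudocount of 10 left 26 genes at least 2-fold higher, as it shrinks changes at low levels. With the replicate number as a block 1535 genes were higher and 1771 lower; residual correlations of libraries sharing a number were -0.0379, -0.00235 and 0.0551.

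With an estimated correlation all 15 list calls ended: stem cells, late stages, integrated stress response and apoptosis (0.178 each), differentiating spermatogonia (0.0876), meiotic prophase (0.0986), piRNA pathway (0.185), Sertoli cells, cell cycle, inflammation and early response (0.188 each), Leydig cells and recombination repair (0.16 each), macrophages (0.311) and excision repair (0.418). fry called myoid cells (0.0112) and p53 targets (0.01) and did not call excision repair (0.0766) or inflammation (0.0521).

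Leaving out 1 library gave 916 to 1764 higher and 1278 to 1792 lower genes, 33 to 53 and 273 to 331 at least 2-fold, and log2 fold changes of Eif5 from -0.3582 to -0.2675. List adjusted p ran from 0.0497 to 0.541 for progenitors, 0.099 to 0.905 for endothelial cells, 0.00494 to 0.681 for erythroid cells, 0.04 to 0.325 for mesothelium, 0.143 to 0.905 for ER chaperones, 0.0179 to 0.0569 for apoptosis, 0.00242 to 0.0554 for excision repair, 0.000103 to 0.68 for ribosomal proteins, 0.00642 to 0.0978 for inflammation, 0.000261 to 0.807 for mitochondrially encoded genes and 0.00954 to 0.0832 for early response. Directions turned for ribosomal proteins without control 2 (0.513), control 3 (0.68) or cKO 2 (0.589), mitochondrially encoded genes without control 2 (0.807), endothelial cells without control 3 (0.896), and ER chaperones without control 3 (0.618) or cKO 2 (0.666).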

Other observations

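The tests of the germ cell lists, of the repair list against the piRNA and cell cycle lists, and of the integrated stress response list were chosen only after results were seen. Their permutation p-values and the intervals of differences of medians came from resampling genes. Genes of a list are not independent replicates, and the spread between libraries does not enter these values. X-linked genes were among the largest falls. Of 726 X-linked genes tested 122 were lower in cKO (16.8%), against 1689 of 16488 autosomal genes (10.24%), an odds ratio of 1.77 (interval 1.435 to 2.168, Fisher's exact p = 1.2e-07, over genes, which are not independent replicates). In the lowest group by mean level the odds ratio was 4.045, and in the middle and highest groups it was 1.175 and 1.127 (Fisher's exact p = 0.34 and 0.61). X-linked genes were also called higher somewhat more often (12.12% against 9.674%). Rhox13 (log2 fold change -1.58), Fmr1nb (-1.56), Tex11 (-1.29) and Taf7l (-1.04) were among 61 that fell at least 2-fold, and were chosen after their values were seen. Several X-linked families have similar copies, so their values are uncertain.

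The stem cell list, with 5 of 16 members higher (0 under the Sertoli scaling, with a median of -0.02; adjusted p = 0.178 with an estimated correlation), did not share the fall of the meiotic list, and their medians differed by 1.727 in log2 (interval 1.352 to 1.983, permutation p = 1e-05, the smallest that 100000 permutations can give). An equal loss of every germ cell type predicts no difference only where both lists are expressed in germ cells alone. Whether somatic cells add to the stem cell list was not tested, so the permutation cannot exclude this explanation. Without any 1 library the difference was 1.537 to 1.82, so 1 library did not make it. The rise was not shared by all of the stem cell list: 13 of its 16 members had a positive change and 3 a negative one. Of the 16, 11 were not called, and edgeR called 1 lower. Fewer cells at later stages relative to stem cells could give the values of the 2 lists, and so could changed transcription per cell. Counts of cells by stage on sections of the same testes would tell these apart.

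The recombination and Fanconi repair list fell. After a trend on gene length, GC content and mean level was removed its median was -0.413, outside the range of random lists (-0.08 to 0.15), so these properties did not make it. The list's median before that correction differed from that of the germline piRNA list by 0.007 (interval -0.124 to 0.229, permutation p = 0.56). From that of the cell cycle list it differed by 0.036 (interval -0.148 to 0.237, permutation p = 0.65). Both permutations were 1-sided, for a lower median of the repair list. A fall in repair gene transcription within cells could therefore not be told from fewer germ cells or fewer dividing cells. Sorted spermatogonia of 1 stage would be needed.

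In the integrated stress response list 2 members, Chac1 and Slc7a3, lay above 0.964, the log2 fold change of Gdnf and the highest among 30 Sertoli and Leydig genes. Each member was set against Gdnf in a 1-sided moderated t test with the errors of both, adjusted over the 36 members. The adjusted p of this test was 5.6e-05 for Chac1 and 0.00025 for Slc7a3. A larger share of Sertoli and Leydig cell RNA alone would not give these 2 rises. Trib3 (1.04) lay within its error of Gdnf. The other 34 members had a median of 0.316, outside that of random lists (-0.094 to 0.149). It differed by -0.11 from that of the Sertoli and Leydig genes (interval -0.244 to -0.01, from resampling genes), so the median of these members was not above that of those genes. The 1-sided permutation p for a higher median was 0.97, so a larger share of those cells may be enough. Sertoli and Leydig genes exceeded myoid and endothelial genes by 0.521 (interval 0.408 to 0.635, permutation p = 1e-05). An equal rise of every somatic cell type predicts no such difference only where these genes keep their level per cell. That was not tested, so the permutation cannot exclude an equal rise. Protein measures of ATF4 by cell type would place the response.

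Over the 10 ways to divide the libraries, the genotypes gave 1692 higher, 1829 lower, 43 higher 2-fold and 342 lower 2-fold genes. The highest count in any other division was 0, so 1 of 10 divisions reached each real count. A total of 10 divisions is too few for a share under 0.05. The other divisions had both genotypes on each side, so the genotype difference entered their spread. A count of 0 in them is therefore not what libraries without a genotype effect would show. For lists called, 3 of 10 divisions reached the real 15, the highest other being 17. That division set the 3 libraries with the highest mitochondrial shares (7.93% to 9.64%) against the others (4.41% to 6.39%). Genes within 10 Mb of Eif5, where DNA of another strain may flank a floxed allele, were called at an odds ratio of 1.006 (interval 0.6541 to 1.507, Fisher's exact p = 1; 31 of 152 genes).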
